A study of Homo sapiens with 8 samples.

How the data were processed

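Total RNA of A549 cells was labelled with Cy3 and hybridised to Agilent one-colour arrays, per the labels' protocols, 4 after pirfenidone and 4 after PBS. The authors' deposited scanner output holds processed intensity values, background-corrected by Feature Extraction 11.5.1.1 with protocol GE1_1105_Oct12 on array design 026652, per the file headers. The deposited series table holds log2 values. Set against the scanner values it correlated at r = 1 (rounded) on every array over 34080 probes once these had been shifted to the array's 75th percentile and each probe centred on its median over the 8 arrays. Its scale, centring and direction are therefore known from that comparison. Its column medians lay between -0.09 and 0.06, and at 0.45 for pirfenidone replicate 3.

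Here, log2 of the processed signal was taken, spots marked as non-uniform or population outliers were dropped, the spots of a probe were averaged, and the array's 75th percentile over non-control probes was subtracted. From 43118 spots of 34127 probes, 47 probes with no value on some array were left out. A probe was kept if well above background in at least 50% of its spots on at least 4 of the 8 arrays, which left 22470 probes. No probe was saturated. Probes were named through their RefSeq accession, without version, in a gene table of assembly GRCh38.p14; 26377 probes matched and 7750 kept their identifier. The file headers name build hg19, so no coordinates are given. The brightest probe stood for each gene, giving 17940 genes, 14669 of them with a symbol. Different probes were called in opposite directions for 7 of 3778 genes with several kept probes.

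Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the group alone) with Benjamini-Hochberg adjustment at 0.05. A gene dim on all arrays of a group has only a bound: its fold is the bright group's mean against the mean, per array, of the higher of the gene's own signal and the lowest signal well above background. Such folds are written "at least". This held for 44 genes in PBS and 45 in pirfenidone. Gene lists, 34 in number, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it, adjusted over the 34 lists. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest estimated increases and 12 largest estimated decreases among genes with a symbol that passed and moved the same way in all 4 same-numbered pairs. It took the 4 members of smallest p from each list that passed or had at least 3 genes past the threshold. It also took a fixed panel that included TGFB1, CCN2, FN1, VIM, CDH1, CYP1A1, CYP1B1, CD274, MKI67, CDKN1A, HMOX1, GAPDH and ACTB. It named 128 genes, of which 106 passed; a few of them are not reported here.

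On simulated data of 17940 genes with 200 changed, made from the spread of these arrays, the comparison of all 8 arrays recovered 31% of genes changed by 1 on the log2 scale and 75% of those changed by 2, with 3 unchanged genes called. Without pirfenidone replicate 3 it recovered 49% and 91%, with 7 unchanged genes called. The real comparison called 3016 genes, far more than the 200 changed in the simulation, and the adjusted threshold depends on that share. The simulated noise was also independent between genes. These rates therefore do not give the share of real changes recovered.

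Alternatives were centring on the array median, quantile normalization, normexp background correction with an offset of 50 with either scaling, the authors' series table, other filters on dim probes, other rules for several probes, blocks for replicate number and slide (statmod 1.5.0 for the random block), a variance trend with robust estimation, array weights, and leaving out each array or same-numbered pair. Normexp used median spot and background signals, since the files used here have no mean signal column. Scan day as a block, single slides and days, the direction on each slide of genes called from the other slides, and the estimated correlation without pirfenidone replicate 3 were added after seeing the data.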

Results

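RNA of 8 samples of A549, an established human lung adenocarcinoma cell line, was hybridised to one-colour microarrays. Cells received 1.5 mg/ml of pirfenidone, a drug used against lung fibrosis, or an equal volume of phosphate-buffered saline (PBS) for 24 h, with 4 arrays per group. The comparison asks which transcripts differ between pirfenidone and PBS. Of 34127 probes, between 63.3% and 69.0% were well above background on each array, and the 75th percentile of the processed signal lay between 1505 and 2343 intensity units. The number of arrays limits the precision. The labels do not say whether replicates came from separate cultures or passages, so the p-values measure the spread between these arrays, which may be technical. Values below are log2 differences of pirfenidone minus PBS ± SE over 4 arrays per group, with limma's Benjamini-Hochberg adjusted p, unless another measure is named.

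After pirfenidone, 31 of 37 genes of G1/S transition and DNA replication and 24 of 36 of G2/M and mitosis fell. In 3 other gene lists, 17 of 31 integrated stress response targets rose, as did 12 of 30 p53 targets, where 1 fell, and 16 of 31 immediate early genes. The lists share some genes that rose. SESN2 and GDF15 count among both stress response and p53 targets, and ATF3 among both stress response targets and immediate early genes. These 5 lists passed a set test with a preset correlation between genes, and none did with an estimated one (adjusted p = 0.31 for each). Among 17940 genes tested, 1618 rose and 1398 fell, and 932 of the former and 813 of the latter changed at least 2-fold. The array of pirfenidone replicate 3 differed from the other 3 pirfenidone arrays. Without it, 7329 genes passed, 3732 higher and 3597 lower, and these included 3012 of the 3016. Leaving out any other single array gave between 1169 (without PBS replicate 2) and 1941 genes (without pirfenidone replicate 1). At 2-fold, 3036 genes passed without pirfenidone replicate 3 and between 925 and 1260 without any other. Genes that rose made up 53.7% of calls, against 32.4% with arrays centred on their median and 39.2% after normexp background correction.

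The 8 arrays lay on 3 slides that each held both groups, and on 2 scan days. With slide as a block 2672 genes passed, and with scan day as a block 3118. Slides 1 and 2 held 1 array per group, which allows no test within them. Of 763 genes called from slides 2 and 3 alone, 97.9% had the same direction on slide 1, as did 99.5% of 205 genes on slide 2 and 96.1% of 2587 on slide 3, each called from the other slides. Over all 17940 genes the shares lay between 73.6% and 80.5%, and with no change the share is 50%. Slide 3 alone, with 2 arrays per group, gave 0 genes by limma, and 1773 at an unadjusted p below 0.05. The second scan day alone, with 3 arrays per group, gave 763 genes, of which 734 were among the 3016.

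NGFR, a neurotrophin receptor well above background on 1 of 4 PBS arrays, rose by 5.78 ± 0.96 (adjusted p = 0.00803), with 9.10 in pirfenidone replicate 3 and 4.68 without it. MMP1, an interstitial collagenase, was not well above background in PBS and rose at least 14.7-fold (adjusted p = 0.00366). The thioesterase OLAH, the transcription factor TBX4 and COX8C, a cytochrome c oxidase subunit, were likewise dim in PBS and rose at least 4.81-fold, 3.24-fold and 7.81-fold. KLHDC7B rose by 4.59 ± 0.64 and SPX, which encodes the peptide spexin, by 3.67 ± 0.47, with 2 and 3 of 4 PBS arrays well above background. The stress-induced transcription factors DDIT3 and ATF3 rose by 3.78 ± 0.57 and 3.50 ± 0.65. CHAC1, a glutathione-degrading enzyme, rose by 3.49 ± 0.34, TXNIP, a thioredoxin inhibitor, by 3.53 ± 0.40 and SH2D3C by 3.50 ± 0.19, the latter 2 measured on 2 and 3 PBS arrays. Without pirfenidone replicate 3, KLHDC7B stood at 5.27, DDIT3 at 3.15 and ATF3 at 2.76, and COX8C rose at least 12.4-fold. Adjusted p of the 12 genes with the largest estimated increases was at most 0.0117. For MMP1, OLAH, TBX4 and COX8C that rank rests on PBS signal not well above background. By their bounds alone, OLAH and TBX4 need not exceed CDKN1A, measured on all 8 arrays, at 6.1-fold.

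Among the largest decreases FAM111B, a protease, stood at -5.0 ± 0.69 or 32.0-fold (adjusted p = 0.00411). SPC25, a kinetochore component, stood at -4.71 ± 0.40, E2F8, a cell cycle transcription factor, at -4.66 ± 0.86 and RRM2, a ribonucleotide reductase subunit, at -4.34 ± 0.87. The condensin subunits NCAPG and NCAPH, each well above background on 1 of 4 pirfenidone arrays, stood at -3.78 ± 0.82 and -3.52 ± 0.96 (adjusted p = 0.0197 and 0.0405), and NCAPH did not pass with slide as a block (adjusted p = 0.0631). The serotonin receptor HTR2B and the epithelial transcription factor EHF were not well above background after pirfenidone and fell at least 15.3-fold and 5.80-fold. Their place among the largest decreases rests on that dim signal. ZBED2 stood at -4.65 ± 0.72, the tight junction protein CLDN2 at -4.00 ± 0.67, the small RNA SCARNA13 at -3.64 ± 0.39 and RIBC2 at -3.59 ± 0.51. After pirfenidone ZBED2 was well above background on 1 of 4 arrays and E2F8 on 2. Without pirfenidone replicate 3, FAM111B stood at -5.77, RRM2 at -5.35 and E2F8, measured on 1 of the other 3, at -5.50. ZBED2, NCAPG and NCAPH were not well above background on those 3 and were lower by at least 14.3-fold, 22.1-fold and 5.51-fold.

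**Figure D1:**
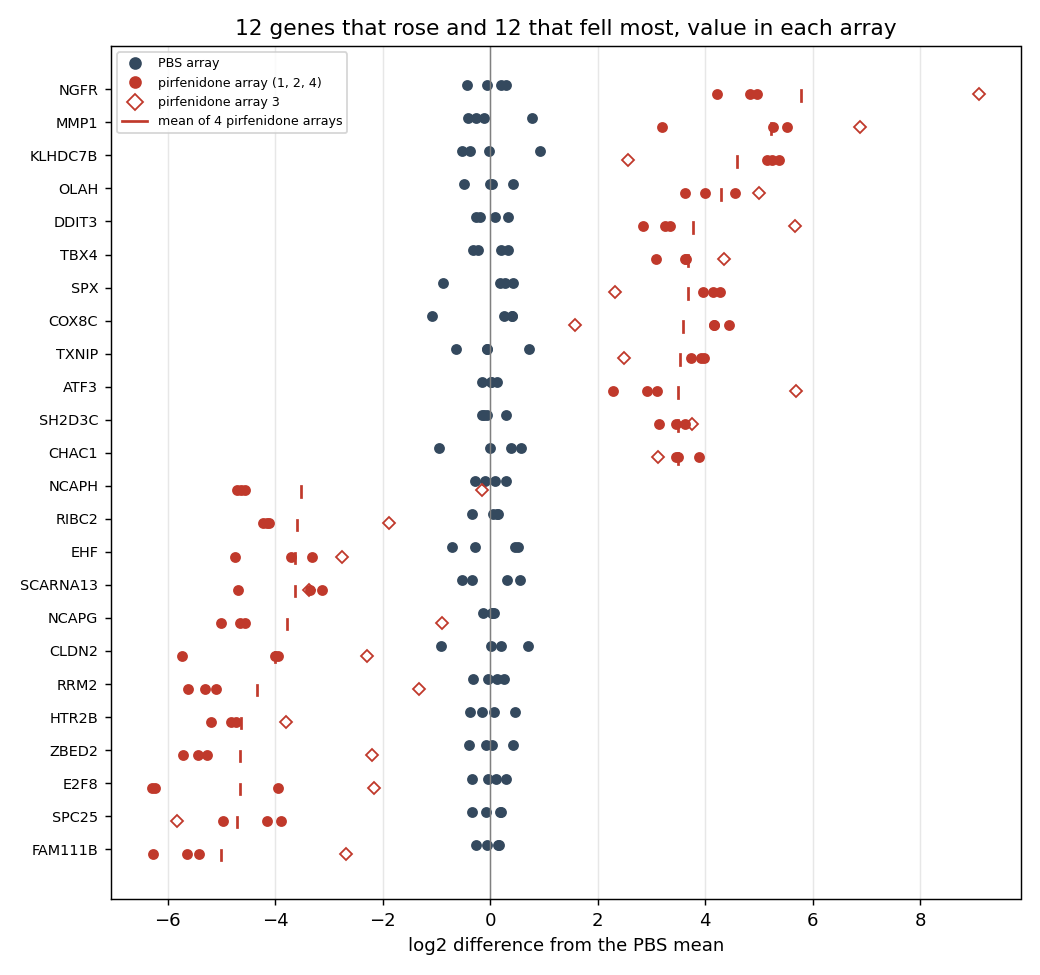
Log2 difference from the PBS mean (x axis) of the 12 genes with the largest estimated increase and the 12 with the largest estimated decrease under the naming rule. A point stands for each array, 4 PBS and 4 pirfenidone, and a vertical bar for the pirfenidone mean. For genes dim in a group, the rank rests on signal not well above background. Pirfenidone replicate 3, the open diamond, lies at 9.10 for NGFR and at -0.16 for NCAPH, apart from the other 3 pirfenidone arrays.

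Of 37 tested genes of G1/S transition and DNA replication, 31 fell and none rose, with a median of -2.05 (camera adjusted p = 4.81e-18). The polymerase clamp PCNA stood at -1.59 ± 0.21, the clamp loader subunit RFC3 at -2.68 ± 0.26, the primase PRIM1 at -1.89 ± 0.17 and the chromatin assembly factor CHAF1B at -1.95 ± 0.31. Of 36 genes of G2/M and mitosis, 24 fell and none rose, with a median of -2.06 (camera adjusted p = 4.81e-18). The spindle checkpoint kinase BUB1B stood at -2.88 ± 0.17, the mitotic kinesin KIF23 at -2.75 ± 0.21, the spindle protein ASPM at -2.57 ± 0.19 and the cyclin CCNB2 at -1.74 ± 0.25. Adjusted over the list alone, 37 and 36 genes passed, and as many fell without pirfenidone replicate 3. Neither list passed with an estimated correlation, at adjusted p = 0.31 for both. The mean of the G1/S list was between -2.93 and -2.46 in 3 pirfenidone arrays and -0.66 in replicate 3, and that of the G2/M list was between -3.04 and -2.42 and -0.55. MKI67, a proliferation marker, had a difference of -2.07 ± 0.82 that did not pass (adjusted p = 0.119), and one of -3.00 without pirfenidone replicate 3 (adjusted p = 0.000127).

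Among 22 tested genes of the list of replication-dependent histones, 2 fell and 1 rose, with a median of -1.14 (camera adjusted p = 0.00902, and adjusted p = 0.66 with an estimated correlation). Adjusted over the list alone, the same numbers passed. H2AC4 stood at -2.28 ± 0.57 and H1-3 at -1.94 ± 0.53, and neither passed with slide as a block (adjusted p = 0.0544 and 0.0647). Without pirfenidone replicate 3 they stood at -2.93 and -2.54. H3C4 had a difference of -1.91 ± 0.91 (adjusted p = 0.186), and one of -2.87 without that array (adjusted p = 0.00232). The list's mean was 0.99 in pirfenidone replicate 3 and between -2.15 and -1.28 in the other 3, and the PBS arrays ranged from -0.71 to 0.60. Without replicate 3, 17 histone genes fell, and without pirfenidone replicate 1 the list did not pass (adjusted p = 0.0597).

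Targets of the integrated stress response, which is driven by the transcription factor ATF4, rose in 17 of 31 tested genes and fell in none, with a median of 1.06 (camera adjusted p = 1.17e-09, and adjusted p = 0.31 with an estimated correlation). SESN2, an inhibitor of mTORC1 signalling, rose by 2.55 ± 0.20, DDIT4, another such inhibitor, by 2.11 ± 0.16, and the pseudokinase TRIB3 by 1.92 ± 0.21. Of 23 unfolded protein response genes, 5 rose and none fell, with a median of 0.65 (camera adjusted p = 0.000153, and adjusted p = 0.31 with an estimated correlation). The co-chaperone DNAJB9 rose by 2.55 ± 0.21, HERPUD1, a part of endoplasmic reticulum degradation, by 1.64 ± 0.18, XBP1 by 1.06 ± 0.21, CREB3L2 by 0.99 ± 0.19 and PDIA4 by 0.60 ± 0.16 (adjusted p = 0.0613 with slide as a block). Adjusted over the list alone, 19 and 9 genes rose. The mean of the stress response list was 0.61 in pirfenidone replicate 3 and between 1.42 and 1.55 in the other 3 arrays, and that of the unfolded protein response was 0.28 against 0.65 to 0.86. Without replicate 3, 27 and 16 genes rose. Of 20 heat shock genes none passed, with a median of -0.03, a mean of 0.10 and a camera direction of down (adjusted p = 0.488).

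Of 30 p53 targets, 12 rose and 1 fell, with a median of 0.78 (camera adjusted p = 1.36e-07, and adjusted p = 0.31 with an estimated correlation). CDKN1A, a cyclin-dependent kinase inhibitor, rose by 2.61 ± 0.31 (adjusted p = 0.00235), the antiproliferative factor BTG2 by 1.68 ± 0.20 and the kinase PLK3 by 1.63 ± 0.14, and the polymerase POLH fell to -0.78 ± 0.18. Among 30 apoptosis regulators 8 rose and none fell, with a median of 0.34 (camera adjusted p = 0.00913, and adjusted p = 0.31 with an estimated correlation). The proapoptotic BBC3, HRK and PMAIP1 rose by 2.38 ± 0.49, 1.66 ± 0.21 and 1.58 ± 0.29, and the death receptor TNFRSF10B by 1.22 ± 0.20. MCL1, a survival factor, rose too, by 0.99 ± 0.25, so the list's direction is not that of proapoptotic genes alone. BBC3 and TNFRSF10B also count among the 12 p53 targets. Adjusted over the list alone, 19 p53 targets rose and 1 fell, and 12 apoptosis regulators rose and 1 fell. Leaving out pirfenidone replicate 3, 20 p53 targets rose and 1 fell, and 14 apoptosis regulators rose and 4 fell. The means in pirfenidone replicate 3 were 0.77 for p53 targets, against 0.91 to 1.09, and 0.75 for apoptosis regulators, against 0.23 to 0.39. The apoptosis list did not pass without that array (adjusted p = 0.128).

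Immediate early genes, which are induced within minutes by many stimuli, rose in 16 of 31 tested and fell in none, with a median of 0.89 (camera adjusted p = 4.82e-09, and adjusted p = 0.31 with an estimated correlation). KLF4 rose by 1.84 ± 0.17, the phosphatase DUSP6 by 1.79 ± 0.28, the mRNA-decay factor ZFP36 by 1.73 ± 0.16 and JUNB by 1.47 ± 0.26. Short-lived transcripts, listed as a sign of RNA quality, rose in 4 of 12 and fell in none, with a median of 0.64 (camera adjusted p = 0.00902, and adjusted p = 0.31 with an estimated correlation). These 4 were ZFP36, JUN at 1.31 ± 0.24, the survival factor MCL1 at 0.99 ± 0.25 and IER3 at 0.70 ± 0.19. Of them ZFP36, JUN and IER3 also count among the 16 immediate early genes, so the 2 lists are not separate results. Adjusted over the list alone, 20 and 5 genes rose. Replicate 3 had the highest pirfenidone means, 1.99 for immediate early genes against 0.83 to 0.94, and 1.17 for short-lived transcripts against 0.40 to 0.86. Without it the immediate early list passed (adjusted p = 2.84e-06) and the short-lived list did not (adjusted p = 0.0677).

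Nuclear genes of oxidative phosphorylation fell in 8 of 36 and rose in none, with a median of -0.36 (camera adjusted p = 2.53e-06, and adjusted p = 0.31 with an estimated correlation). The complex I subunit NDUFB3 stood at -1.38 ± 0.19, the ATP synthase subunit ATP5MC1 at -1.06 ± 0.15 and cytochrome c, CYCS, at -0.80 ± 0.17. The list's mean was -0.39 in pirfenidone replicate 3 and between -0.44 and -0.36 in the other 3. Of 25 cholesterol synthesis genes 3 fell and none rose, with a median of -0.45 (camera adjusted p = 0.0123, and adjusted p = 0.60 with an estimated correlation). These were FDPS at -1.17 ± 0.16, IDI1 at -1.06 ± 0.30 and LSS at -0.73 ± 0.20, while EBP had -1.15 ± 0.41 (adjusted p = 0.0918), and -1.61 without pirfenidone replicate 3 (adjusted p = 9.28e-05). The list's mean was 0.25 in pirfenidone replicate 3 and between -0.76 and -0.54 in the other 3, and 16 of its genes fell without that array. Without pirfenidone replicate 1 the cholesterol list did not pass (adjusted p = 0.0503). Of 19 fatty acid synthesis genes 2 fell and 1 rose, with a median of -0.38 (camera adjusted p = 0.00902, and adjusted p = 0.31 with an estimated correlation). The desaturase FADS2 stood at -1.20 ± 0.27 and the lipogenic regulator SREBF1 at -0.90 ± 0.25, where 1 of 2 probes had the other sign. ACSS2, an acetyl-CoA synthetase, rose by 0.58 ± 0.15, and the fatty acid synthase FASN had -1.15 ± 0.34 (adjusted p = 0.0504), and -1.50 without pirfenidone replicate 3 (adjusted p = 0.000342). Adjusted over the list alone, 9 oxidative phosphorylation genes and 1 cholesterol synthesis gene fell, and 5 fatty acid synthesis genes fell and 1 rose. Over the other 7 arrays, without pirfenidone replicate 3, 18 oxidative phosphorylation genes fell and none rose, and 8 fatty acid synthesis genes fell and 1 rose.

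Hypoxia targets rose in 5 of 24 and fell in 1, with a median of 0.58 (camera adjusted p = 0.0284, and adjusted p = 0.31 with an estimated correlation), and 6 rose and 1 fell adjusted over the list alone. Of these targets 12 rose and 2 fell without pirfenidone replicate 3. ANGPTL4, a lipoprotein lipase inhibitor, rose by 2.35 ± 0.42, MXI1, a MYC antagonist, by 1.69 ± 0.16, ANKRD37 by 0.93 ± 0.17 and NDRG1 by 1.40 ± 0.36, as did DDIT4, and the glycolytic regulator PFKFB3 fell to -1.25 ± 0.35. With slide as a block NDRG1 and PFKFB3 did not pass (adjusted p = 0.0633 and 0.0589). The mean was 0.19 in pirfenidone replicate 3 and between 0.52 and 0.58 in the other 3, and the list did not pass without pirfenidone replicate 1 (adjusted p = 0.0597). Glycolysis did not pass camera (adjusted p = 0.102) and passed fry downward (adjusted p = 0.00939), with PFKFB3 and PGAM1, at -0.95 ± 0.14, lower of 22 genes, and 6 lower and 1 higher without pirfenidone replicate 3. Fatty acid oxidation and PPAR targets did not pass camera either (adjusted p = 0.354), with ANGPTL4 and the lipid droplet protein PLIN2, at 0.89 ± 0.26 (adjusted p = 0.0629 with slide as a block), higher of 23 genes and 3 lower. Among those lower were HADH at -0.89 ± 0.18 and PDK4 at -1.11 ± 0.30.

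Extracellular matrix and remodelling genes rose in 5 of 31 and fell in none, also adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0239, and adjusted p = 0.37 with an estimated correlation). Besides MMP1, the membrane protease MMP14, measured on 2 of 4 PBS arrays, stood at 1.65 ± 0.45, the urokinase receptor PLAUR rose by 1.50 ± 0.25, the collagen COL7A1 by 1.13 ± 0.20 and the metalloproteinase inhibitor TIMP3 by 2.86 ± 0.80 (3.68 without pirfenidone replicate 3). With slide as a block MMP14 did not pass (adjusted p = 0.0754). Matrix genes numbered 11 that rose and 1 that fell without pirfenidone replicate 3, with a median of 0.36. The matrix list did not pass without pirfenidone replicate 1 (adjusted p = 0.0597), pirfenidone replicate 2 (adjusted p = 0.0642) or PBS replicate 4 (adjusted p = 0.0573). TGF-beta response genes rose in 4 of 29 and fell in 2, with a median of 0.49 (camera adjusted p = 0.0490, and adjusted p = 0.60 with an estimated correlation), and 8 rose and 2 fell adjusted over the list alone, and 11 and 2 without pirfenidone replicate 3. Those that rose were ANGPTL4, JUNB and the differentiation inhibitors ID1 and ID3, at 0.67 ± 0.14 and 0.62 ± 0.14. CCN2, a matricellular growth factor, fell to -1.51 ± 0.29 (adjusted p = 0.0129) and the ligand TGFB2 to -1.40 ± 0.36. The TGF-beta list did not pass with slide as a block (adjusted p = 0.0612) or without pirfenidone replicate 1 (adjusted p = 0.113), pirfenidone replicate 3 (adjusted p = 0.117), PBS replicate 2 (adjusted p = 0.0870) or PBS replicate 4 (adjusted p = 0.102). In pirfenidone replicate 3 its mean was 0.65 against 0.14 to 0.55, and that of the matrix list 0.38 against 0.44 to 0.77. Mesenchymal markers did not pass (adjusted p = 0.257), with SNAI1 and ITGA5 higher of 17, at 1.61 ± 0.37 and 0.93 ± 0.24. Epithelial markers did not pass (adjusted p = 0.618), with OCLN higher and TJP3 lower of 18, at 1.53 ± 0.22 and -1.45 ± 0.42, TJP3 measured on 3 of 4 pirfenidone arrays. The differences for TGFB1 (0.48 ± 0.15, adjusted p = 0.0562), VIM (0.34 ± 0.23), FN1 (-0.48 ± 0.57) and CDH1 (0.54 ± 0.37) did not pass. Without replicate 3, TGFB1 passed at 0.53 (adjusted p = 0.0115) and CDH1 at 0.91 (adjusted p = 0.00876), and FN1 did not pass at -0.99 (adjusted p = 0.0949).

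Drug metabolism and xenobiotic transport genes fell in 5 of 24 and rose in 2, also adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.0425, and adjusted p = 0.31 with an estimated correlation). The retinoic acid hydroxylase CYP26A1 stood at -3.25 ± 0.62 (-3.90 without pirfenidone replicate 3) and the efflux pump ABCG2 at -2.55 ± 0.44. AOX1 and UGT2B7 stood at -1.44 ± 0.29 and -1.56 ± 0.41, and CYP4F3 rose by 1.23 ± 0.23. ABCC3 was higher too, and neither it nor UGT2B7 passed with slide as a block (adjusted p = 0.0636 and 0.0579). The mean was -0.31 in pirfenidone replicate 3 and between -0.68 and -0.47 in the other 3, and the list did not pass without that array (adjusted p = 0.154), without pirfenidone replicate 2 (adjusted p = 0.0660), PBS replicate 1 (adjusted p = 0.0615) or PBS replicate 3 (adjusted p = 0.0540), or with normexp (adjusted p = 0.204). Aryl hydrocarbon receptor targets did not pass (adjusted p = 0.182), with TIPARP at 0.88 ± 0.25 (adjusted p = 0.0471, and 0.0741 with slide as a block) and ABCG2 and the quinone reductase NQO1 lower, NQO1 at -1.0 ± 0.19. CYP1A1 (-0.17 ± 0.34) and CYP1B1 (0.22 ± 0.39) did not pass, nor did they at -0.51 and 0.48 without pirfenidone replicate 3. NRF2 targets did not pass (adjusted p = 0.354), with 3 of 28 higher and 2 lower. Haem oxygenase HMOX1 rose by 0.60 ± 0.15 (adjusted p = 0.0299). The transporter ABCC3, with 1 of its 2 probes of the other sign, stood at 0.89 ± 0.24, and SRXN1 at 0.54 ± 0.15 (adjusted p = 0.0612 with slide as a block). NQO1 and the glutathione peroxidase GPX2 fell, GPX2 to -2.30 ± 0.60. Metallothioneins and metal handling (adjusted p = 0.484) had HMOX1 and SLC39A14 higher of 14 genes and SLC39A10 and TFRC lower. The zinc transporters SLC39A14 and SLC39A10 stood at 1.01 ± 0.18 and -1.14 ± 0.28, and the transferrin receptor TFRC at -1.01 ± 0.18.

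NF-kB and inflammatory cytokine genes did not pass (adjusted p = 0.569). The chemokines CCL5, dim in PBS, and CXCL8, measured on 2 of 4 PBS arrays, rose at least 5.50-fold and by 2.26 ± 0.46, and CCL2 and CXCL5 stood at -2.89 ± 0.70 (-3.68 without pirfenidone replicate 3) and -0.92 ± 0.25. The mean of this list was 1.23 in pirfenidone replicate 3 and between -0.17 and 0.17 in the other 3. With all arrays 2 of its genes rose and 2 fell, and without that array 6 and 8. Interferon-stimulated genes (adjusted p = 0.198) had OASL higher, at 1.06 ± 0.24, and OAS3 and IFITM3 lower, at -1.32 ± 0.21 and -1.15 ± 0.32. Antigen presentation and checkpoint ligands (adjusted p = 0.429) had CD276 and HLA-E higher, at 0.72 ± 0.16 and 0.58 ± 0.14, and TAPBP lower, at -0.77 ± 0.14. Leaving out pirfenidone replicate 3, 5 interferon-stimulated genes rose and 7 fell, and 7 antigen presentation genes rose and 5 fell. CD274, which encodes PD-L1, did not pass at 0.79 ± 0.50 (adjusted p = 0.314), with 2.04 in pirfenidone replicate 3 and 0.37 without it (adjusted p = 0.492).

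Ribosomal protein genes passed the set test upward (adjusted p = 0.0118, and adjusted p = 0.71 with an estimated correlation) with none of 36 past the threshold for single genes, also adjusted over the list alone, and a median of 0.22. That call was lost with arrays centred on their median (adjusted p = 0.0738), with quantile normalization (adjusted p = 0.257) and without pirfenidone replicate 3 (adjusted p = 0.151), pirfenidone replicate 1 (adjusted p = 0.0926) or PBS replicate 2 (adjusted p = 0.0578). The mean in pirfenidone replicate 3 was 0.44 against -0.09 to 0.36. Autophagy and lysosome genes did not pass camera (adjusted p = 0.225) and passed fry upward (adjusted p = 0.00156), with 4 of 30 higher and 3 lower, and 11 and 6 without pirfenidone replicate 3. The autophagy genes MAP1LC3B, GABARAPL1 and ULK1 stood at 0.98 ± 0.27, 1.15 ± 0.33 and 0.85 ± 0.24, the lysosomal PSAP at 0.71 ± 0.17, GLA at -1.42 ± 0.33, ATP6V0D1 at -0.86 ± 0.16 and CTSB at -0.76 ± 0.19. With slide as a block MAP1LC3B and GABARAPL1 did not pass (adjusted p = 0.0736 and 0.0926). YAP and SRF targets (adjusted p = 0.0971) had CCN2 and TGFB2 lower of 28, and 9 lower and 3 higher without pirfenidone replicate 3. Alveolar and airway differentiation genes (adjusted p = 0.618) had SFTPD and ETV5 higher, at 1.27 ± 0.31 and 0.84 ± 0.16, and CAV1 lower, at -1.77 ± 0.31. LAMP3, measured on 3 of 4 pirfenidone arrays, had 3.41 ± 1.08 (adjusted p = 0.0644), with -0.32 in pirfenidone replicate 3 and 4.65 without it (adjusted p = 6.14e-05). Markers of fibroblasts (5 tested, adjusted p = 0.840), leukocytes (8 tested, adjusted p = 0.585) and endothelial cells (2 tested, adjusted p = 0.354) did not pass. Of the leukocyte markers CSF1R, measured on 1 of 4 PBS arrays, was higher, at 2.49 ± 0.38, and CD14 lower, at -2.24 ± 0.24. The fibroblast list had a median of 0.08 and a mean of -0.02. GAPDH (-0.01 ± 0.16) and ACTB (0.07 ± 0.19) did not pass, and ACTB changed sign with median centring and with quantile normalization, with or without normexp, and GAPDH with normexp alone.

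In total 17 of 34 lists passed with the preset correlation, 10 upward and 7 downward, and 0 with an estimated one, where the lowest adjusted p was 0.31. Regrouping the arrays with 2 PBS and 2 pirfenidone arrays on each side also passed 2 to 12 lists at the preset correlation. Fry, which tests whether genes move on balance one way without comparing them with other genes, passed 15, of which 13 were among the 17. The 4 that passed camera alone were TGF-beta response (fry adjusted p = 0.0725), cholesterol synthesis (0.244), ribosomal proteins (0.244) and replication-dependent histones (0.350), and the 2 that passed fry alone were glycolysis and autophagy. The median of each of the 17 lists had the same sign on all 3 slides, and 16 passed with slide as a block. As the 17 were chosen for passing on these same arrays, with no slide held out, that agreement was largely built in. Medians on slides 1, 2 and 3 were -2.41, -2.92 and -1.73 for G1/S genes, -2.35, -3.10 and -1.42 for G2/M genes, 1.57, 1.41 and 0.75 for the integrated stress response, and 0.79, 1.09 and 0.67 for p53 targets. Without pirfenidone replicate 3, 12 of the 17 passed, and without pirfenidone replicate 1, 11 lists did. The 8 that passed under every alternative other than the estimated correlation were those of the integrated stress response, unfolded protein response, p53 targets, immediate early genes, oxidative phosphorylation, fatty acid synthesis, G1/S and G2/M. Genes named here from small counts in a list, outside the rule, were chosen after their values were seen.

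**Figure D2:**
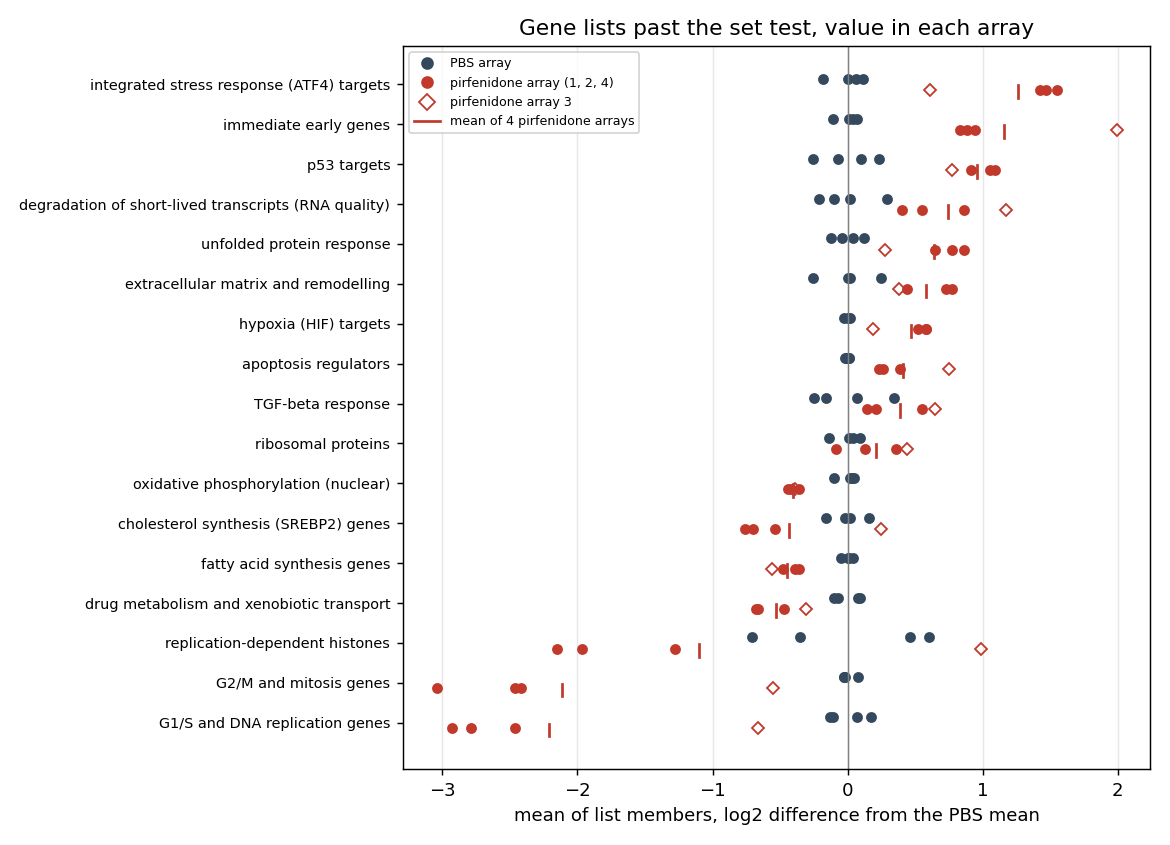
Mean of each gene list's members as a log2 difference from the PBS mean (x axis), for the 17 lists past the set test, with a point per array and a vertical bar at the pirfenidone mean. The G1/S list lies between -2.93 and -2.46 in 3 pirfenidone arrays and at -0.66 in replicate 3, the open diamond.

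Pirfenidone replicate 3 correlated with any other array at no more than r = 0.946 across genes, which are not independent replicates, while PBS arrays correlated among themselves at 0.984 or more and the other 3 pirfenidone arrays at 0.982 or more. On the first principal component, 45.3% of the variance, it lay at -32.8, outside PBS arrays at -55.5 to -35.4 but nearer to them than to the other pirfenidone arrays, at 62.0 to 75.6. On the second, 32.0% of the variance, it lay at 118.6, with the other arrays between -30.6 and 2.2. Its change from PBS correlated with the mean change of the other 3 at r = 0.28 over 17940 genes.

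**Figure D3:**
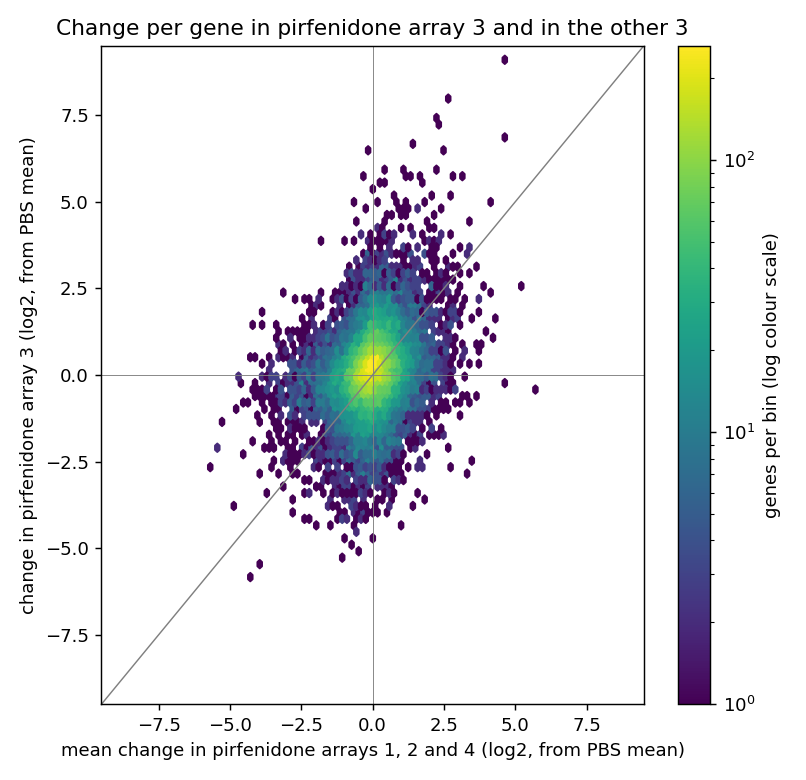
Change from the PBS mean in pirfenidone replicate 3 (y axis, log2) against the mean change in pirfenidone replicates 1, 2 and 4 (x axis, log2) for 17940 genes, binned, with colour for genes per bin on a log scale and a line of equality. The changes correlate at r = 0.28.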

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

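The tests of a wrong label and of a weaker response were chosen after the result was seen. Of 342 values tested for an array far from the other 3 of its group, 39 passed, and in 27 the array was pirfenidone replicate 3. Independent values would give about 1 in 20, or 17, by chance. These values are not independent, as lists and genes share the same arrays and many genes were named for their difference. The 17 is therefore only a rough guide.

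Pirfenidone replicate 3 stood apart on both principal components, with gaps of 0.87 and 0.92 of the group's range, and was lowest for the integrated stress response (0.86), fatty acid oxidation (0.9) and hypoxia lists (0.83) and highest for immediate early genes (0.9). Its root mean square distance was 1.09 from the PBS mean and 1.2 from the other pirfenidone arrays, and its mean correlation 0.942 with PBS arrays and 0.93 with its own group, while its change from PBS had a spread of 0.75 (log2) shared by the 2 brightest probes of a gene, over 3778 genes, which noise of single probes does not raise, against at most 0.25 in a PBS array, and of 0.71 after the best-scaled change of the other 3 was taken out, against at most 0.3 in those. Bootstrap intervals over genes of the excess over 1.5 times those highest values were 0.32 to 0.41 and 0.2 to 0.3, which argues against a PBS sample under the wrong label and a uniformly weaker response as the whole cause, unless RNA damage changed whole transcripts. That change correlated at 0.49 between the 2 probes, against 0.68 to 0.76 in the other pirfenidone arrays (bootstrap interval of the difference from the lowest -0.23 to -0.15). A fault acting probe by probe predicted such a loss and may account for part of the pattern, while damaged RNA and another treatment or handling stay open and no biological explanation was tested. The slope fitted to spike-in control RNAs was lowest on this array, 0.9094 against 0.9568 to 0.9985. The fit's intercept was the highest, -0.038 against -0.743 to -0.368. Its 75th percentile signal, 1505, was the lowest, next to 1577 in pirfenidone replicate 1. None of these measures was flagged as far from the group, and their link to the pattern was not tested.

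In single genes, pirfenidone replicate 3 was the highest of its group for NCAPH (0.97), RIBC2 (0.95), NCAPG and H2AC4 (0.89), BBC3, ATP6V0D1, ATP5MC1, CCL2 and RRM2 (0.88), NQO1, EBP and ZBED2 (0.87), FADS2 (0.86), and NGFR, GLA and H1-3 (0.85). It was the lowest for KLHDC7B (0.92), COX8C and ABCC3 (0.91), and SPX and TNFRSF10B (0.84). Pirfenidone replicate 1 was far from the others for RFC3 (0.93), PRIM1 (0.88), SCARNA13 (0.85) and CD276 (0.83). Among PBS arrays, replicate 1 was far for MCL1 (0.92), COX8C (0.9) and FDPS (0.89), replicate 2 for TGFB1 (0.96), replicate 3 for ALDH3A1 (0.91), TFRC (0.87) and SLC39A14 (0.85), and replicate 4 for the G2/M list (0.84).

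The real split of the 8 arrays was the 1 split of 35 that gave as many genes, 3016, or as many genes at 2-fold, 1745. The highest other split gave 1 in each case. With 35 splits the smallest share that can be reached is 2.86%, so a chance division of the arrays is unlikely for both counts but not excluded. Every other split also puts both groups on each side, which widens the spread and lowers its calls. For gene lists the real split, with 17, was also the only 1 of 35 with as many, but another split gave 16. That split set PBS replicates 1, 3 and 4 with pirfenidone replicate 4, so it still carried part of the treatment difference. The margin of 1 list over it therefore does not measure chance. Splits with 2 PBS and 2 pirfenidone arrays on each side, which balance the treatment, still passed 2 to 12 lists. A list that passes at the preset correlation alone is therefore weak evidence of a treatment effect.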

How the results depend on the processing

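Scan day, single slides or days, the direction on each slide and the estimated correlation without pirfenidone replicate 3 were chosen after seeing the data. Of the 106 named genes that passed, none changed direction under any alternative that tested it, and all 106 passed without pirfenidone replicate 3, against 73 to 84 without any other single array. These 106 were chosen for passing on the same arrays, so a kept direction was largely built in and is no independent support. A gene that moved the same way in all same-numbered pairs cannot change direction when a pair is left out. Without same-numbered pairs 1, 2, 3 and 4, 46, 25, 105 and 30 passed, with normexp 68, with slide as a block 100, on the second scan day 46 and on slide 3 alone 0. Only 87 were tested, and passed, among genes above background on all 8 arrays. Against 3016 genes, 1745 at 2-fold and 17 lists, normexp gave 1087 and 740 genes, normexp with quantile normalization 1069 at 2-fold, no filter on dim probes 1829 genes, and array weights, which gave pirfenidone replicate 3 a weight of 0.07, 9062 and 3226. The second scan day alone gave 763 and 648 genes and slide 3 alone 0 and 0, with fewer arrays. An estimated correlation passed 0 lists, and 0 without pirfenidone replicate 3 (lowest adjusted p = 0.111). Leaving out arrays or same-numbered pairs gave 205 genes (without both arrays of replicate 2) to 7329 (without pirfenidone replicate 3), 205 to 3036 at 2-fold, and 11 to 17 lists. The other alternatives stayed within 1.5 times each count, and the cause was not tested where no fewer arrays explain a change. The median over all genes was 0.05, and -0.10 with median centring or normexp, where calls split into 997 higher and 2076 lower, and 426 and 661, against 1618 and 1398.

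With replicate number as a block, 2305 genes, 1463 at 2-fold, 17 lists and 90 of the 106 genes passed. Deviations of same-numbered arrays from their group means correlated at 0.52, 0.39, -0.04 and 0.20, and 5 of 8 arrays correlated best with their own number. Both arrays of replicate 1 lay on slide 1 and both of replicate 2 on slide 2, while replicates 3 and 4 shared slide 3. Pairing and a shared slide can therefore not be told apart as the source of the higher values. The labels give no pairs and replicate 3 shows no such correlation, so the numbers were not treated as pairs in the main comparison. The rule for named genes did use them, to ask for the same direction in all 4. The random slide block has no set test.

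Values that changed sign were not past the threshold on either side. ACTB was -0.07 with median centring, -0.09 with quantile normalization or array weights and -0.12 with normexp and quantile normalization. With normexp CD274 was -0.07 and GAPDH 0.03, and on the second scan day GAPDH was 0.04 and CYP1A1 0.08. On slide 3 CYP1B1 was -0.24, GAPDH 0.15, CYP1A1 0.16 and FN1 0.33. Over left-out arrays and pairs, ACTB ranged from -0.02 to 0.21, GAPDH from -0.13 to 0.04, CYP1A1 from -0.6 to 0.08 and CYP1B1 from -0.12 to 0.61. List directions turned for epithelial and heat shock genes with normexp (adjusted p = 0.991 each), fibroblast markers with no filter (0.403) and NF-kB genes with array weights (0.760). Over left-out arrays and pairs, where their direction turned too, adjusted p ranged from 0.0948 to 0.972 for heat shock genes, 0.142 to 0.938 for fatty acid oxidation, 0.231 to 0.812 for NF-kB genes and 0.480 to 0.965 for fibroblast markers. The cause was not tested. Array number and signal over background limit what can be called.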

Other observations

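The lists in this part were chosen after the data were seen, and the synthetase test was written before the values it uses were examined. Of 22 tested genes of homologous recombination and crosslink repair, 11 fell and none rose, with a median of -1.82 (camera adjusted p over 5 such lists = 2.16e-09, and adjusted p = 0.29 with an estimated correlation). The exonuclease EXO1 stood at -3.14 ± 0.39, the repair factor XRCC2 at -2.86 ± 0.39, RMI2 at -2.49 ± 0.39 and the helicase BLM at -2.11 ± 0.31 (SE, limma). The mean of the list was -0.25 in pirfenidone replicate 3 and -2.14 over the other 3 arrays, and 21 genes fell without that replicate. Of 10 tested Wnt target genes 4 fell and 2 rose, and the list did not pass (adjusted p = 0.123). The feedback regulators AXIN2, RNF43 and DKK1 stood at -2.87 ± 0.56 (-3.48 without pirfenidone replicate 3), -2.17 ± 0.27 and -2.80 ± 0.33, and SP5 and SOX9 at 1.82 ± 0.27 and 0.96 ± 0.23. Of 15 amino acid transporters none passed with all arrays (camera adjusted p = 0.123), and 9 rose and 2 fell without pirfenidone replicate 3 (adjusted p = 0.00547, and adjusted p = 0.17 with an estimated correlation).

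A rise of cytosolic over mitochondrial aminoacyl-tRNA synthetases was predicted as a hypothesis, since cytosolic ones are known ATF4 targets. Leaving out 4 cytosolic members of the integrated stress response list, the mean log2 difference was -0.14 ± 0.48 (SD) over 15 cytosolic and -0.61 ± 0.45 over 17 mitochondrial genes, a gap of 0.47 (two-sided permutation p = 0.0078, with genes that are not independent replicates). The cytosolic mean itself did not lie above 0, and 5 of 15 were positive, so the gap may come from the mitochondrial genes and the test leaves the ATF4 hypothesis open. Mitochondrial synthetases fell in 3 of 17 and rose in none, with a median of -0.55 (camera adjusted p = 0.00074, and adjusted p = 0.04 with an estimated correlation), among them TARS2 at -1.03 ± 0.21, LARS2 at -0.80 ± 0.18 and EARS2 at -0.73 ± 0.15. Without pirfenidone replicate 3, 11 fell, adjusted p was 0.12 with an estimated correlation, and the means were 0.07 for cytosolic and -0.54 for mitochondrial genes. The cytosolic list as a whole did not pass (adjusted p = 0.827), with SARS1, GARS1 and AARS1 higher and HARS1 lower, AARS1 at adjusted p = 0.0543 with slide as a block.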
